A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

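The samples were 4 RNA preparations of Saccharomyces cerevisiae ATCC 4126, 2 from medium with galactose and 2 from medium with glucose, each measured on 1 Affymetrix yeast array. The deposited values are intensities on a linear scale, 1 per probe set and array, summarised by the authors; the software, background treatment and scaling behind them are not given in the sources used here. The array medians differ by a factor of 1.08 from lowest to highest. By a rule set before the data were examined, the deposited intensities were used without further scaling because that factor was under 1.1.

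Of the probe sets, 60 array controls were left out of the tests, which left 9275. The platform annotation gave 1 gene symbol for 6504 probe sets, several for 328 and none for 2443; the 2443 are unnamed here, not without a gene. All 6504 were matched by gene number to the RefSeq gene table of assembly R64, and 0 symbols changed. No genome build is named with the values, so no coordinates are given. Probe sets of Ty1, Ty2, Ty3, Ty4 and Y prime elements were recognised from the systematic names of their genes, with a list written after the values were seen.

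Values under the 25th percentile of all pooled intensities (18.5) were set to it, and log2 was taken. The 1973 probe sets at this floor on all 4 arrays were not tested, which left 7302. Folds are differences of mean log2 values after the floor; where both arrays of a medium lay under the floor, the fold is a lower bound and is written "at least". Means and SDs are of the intensities before the floor.

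The media were compared per probe set with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, on 2 residual and 4.73 total degrees of freedom) and the Benjamini-Hochberg adjustment, with a threshold of 0.05. There is no block, since the media share only the letter B. For gene lists, the brightest probe set stood for each of 5403 genes, and 35 lists of at least 4 tested members, fixed before the data were examined, were tested with limma's camera with a preset inter-gene correlation of 0.01. Counts adjusted over the list alone use the same p-values with the adjustment over the members. The value of camera with an estimated correlation stands beside each list past the threshold. With 2 arrays per medium, an exact permutation test could not reach 0.05, since the 4 arrays split into pairs in 3 ways.

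Genes were named by a rule set before the data were examined. It takes the GAL list, the up to 12 genes each way with the largest difference among those past the threshold, above the floor on all arrays and apart between the media, and up to 5 bounds each way. From every other list it takes up to 4 members that pass, or else the 2 brightest, and it allows all reference genes. Genes named outside the rule are said to be chosen after their values were seen.

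The steps were tested on simulated data for the galactose and glucose comparison, with 7302 probe sets, 2 arrays each and 200 changed probe sets. Of 50 probe sets per size, 26% of those with a log2 change of 1 were recovered, 96% with a change of 2, and 100% with changes of 3 and 5. Of 176 calls, 15 (8.52%) were false. The simulated spread was drawn independently for each probe set around a smoothed trend, so these shares need not hold for the real arrays. In the real data GIT1, with a difference over 3 on the log2 scale, did not pass. The alternatives were quantile normalization, a shift to a common median, floors at the 10th and 40th percentiles, no floor (log2 of the value plus the 25th percentile), probe sets above the floor on all arrays, eBayes without trend or robust, each array left out, other thresholds, camera with estimated correlation or ranks, fry, and the mean over a gene's probe sets. Leaving out Ty probe sets, keeping only probe sets that name 1 gene, and using 1 probe set per gene were added after the data were seen. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and figures.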

Results

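Transcript levels of the yeast Saccharomyces cerevisiae, strain ATCC 4126, were measured in cultures grown on rich (YP) medium with galactose or with glucose as the sugar. Total RNA was taken at an optical density of 1.0 and measured on Affymetrix yeast arrays, which read each gene with one or more probe sets. There were 4 arrays, 2 per medium, named galactose B, galactose C, glucose A and glucose B after the letters in their labels. The labels do not say whether the letters stand for separate cultures. The p-values of single probe sets therefore measure only the spread between these samples, which may be technical. The camera p-values of gene lists, with the preset correlation, set the members of a list against the other genes. They take the members as nearly independent, so they can be small where the arrays of a medium disagree. The median intensity was 117 on galactose B, 108 on galactose C, 112 on glucose A and 116 on glucose B, and the number of arrays limits the precision of every value. Across 9275 probe sets, which are not independent replicates, Pearson's r of the log2 values was 0.985 between the glucose arrays and 0.971 between the galactose arrays. Galactose B correlated with glucose B at 0.974. The galactose arrays differed by at least 2-fold at 929 probe sets, the glucose arrays at 313, and galactose B differed from glucose B at 448.

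The comparison of the media asks which transcripts differ between growth on galactose and growth on glucose. The galactose permease gene GAL2 (YLR081W) had the highest ratio among probe sets measured on all 4 arrays, 406-fold higher in galactose, at an intensity of 14995 ± 1583 against 37.0 ± 4.04 (SD, n = 2 per medium here and below; adjusted p = 0.00192). The enzymes of the Leloir pathway, which turns galactose into a glucose phosphate, rose with it. Galactokinase GAL1 (YBR020W) was 247-fold higher, at 9446 ± 680.2 against 38.3 ± 2.95 (adjusted p = 0.00192). The epimerase gene GAL10 (YBR019C) was 126-fold higher, at 5604 ± 177 against 44.6 ± 1.59 (adjusted p = 0.00207). The uridylyltransferase gene GAL7 (YBR018C) was at least 271-fold higher, at 5020.4 ± 429 against 11.4 ± 3.89, both glucose arrays lying under the floor of 18.5 (adjusted p = 0.00192).

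The regulators of the pathway changed less. GAL3 (YDR009W), the galactose sensor, was 12.7-fold higher (adjusted p = 0.0469), and GAL80 (YML051W), which holds the activator Gal4 inactive, was 7.26-fold higher (adjusted p = 0.0433). The activator gene GAL4 (YPL248C) stood at 39.8 ± 5.20 in galactose and 31.5 ± 6.96 in glucose and did not pass (adjusted p = 0.734). Of the phosphoglucomutase genes, PGM1 stood at 381 ± 19.3 and 387 ± 77.0. PGM2 stood at 8042 ± 3068 and 3959.5 ± 201, with an adjusted p of 0.0422 adjusted over the list alone and of 0.533 over all probe sets. Of the 9 listed Leloir and regulatory genes, 6 passed over all probe sets and 7 adjusted over the list alone, and the median change was 12.7-fold (log2 3.66, camera adjusted p = 4.61e-19, and adjusted p = 0.365 with an estimated correlation). GAL3 and GAL80 lost their calls after quantile normalization, with the floor at the 10th percentile, with no floor, when the probe sets of Ty elements were left out of the adjustment, among probe sets that name 1 gene and with 1 probe set per gene.

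Among 5 other genes reported as Gal4 targets, the dehydrogenase gene GCY1 (YOR120W) was 8.21-fold higher, at 5064 ± 1810.0 against 597 ± 7.81 (adjusted p = 0.0451), and it lost its call under the same settings and with the arrays shifted to a common median. The uracil permease gene FUR4 (3.71-fold), the cyclin gene PCL10 (2.94-fold) and the aminopeptidase gene LAP3 (1.88-fold) had both galactose arrays above both glucose arrays and passed only adjusted over the list alone; they and MTH1 are named here after their values were seen. MTH1, a regulator of glucose transport, stood at 782 ± 103 in galactose and 1106 ± 364 in glucose (adjusted p = 0.738). The list's median change was 2.94-fold (camera adjusted p = 5.25e-05, and adjusted p = 0.439 with an estimated correlation). Outside the lists, SDD1 (YEL057C) was 20.3-fold higher, at 428 ± 12.5 against 21.1 ± 1.86 (adjusted p = 0.0210). NFG1 (YLR042C) was at least 3.99-fold higher, with glucose under the floor (adjusted p = 0.0343), and lost its call with the floor at the 40th percentile, without the Ty probe sets, among probe sets that name 1 gene and with 1 probe set per gene.

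Several genes for glucose uptake were lower in galactose. The hexose transporter gene HXT4 (YHR092C) was 33.6-fold lower, at 23.2 ± 5.51 against 767 ± 21.3 (adjusted p = 0.0210), and HXT2 (YMR011W) was 24.4-fold lower, at 192 ± 98.4 against 4353 ± 160.2 (adjusted p = 0.0362). Of 9 transporter genes tested, 6 had both galactose arrays below both glucose arrays, 2 passed over all probe sets and 5 passed adjusted over the list alone. The further 3 were HXT3 (3.09-fold lower), HXT6 (2.48-fold) and HXT7 (2.39-fold), chosen after their values were seen; HXT6 and HXT7 are nearly identical, so their signals cannot be separated. HXT1, also chosen afterwards, lay under the floor in galactose and at 42.7 ± 23.7 in glucose (adjusted p = 0.579). How much glucose was left in the glucose samples is not known here. The folds therefore need not be those of galactose against ample glucose. The list fell with a median change of 2.39-fold (camera adjusted p = 1.87e-05, and adjusted p = 0.439 with an estimated correlation). HXT2 lost its call with no floor, without the Ty probe sets, among probe sets that name 1 gene and with 1 probe set per gene, while HXT4 kept its call in all of these.

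The list of 18 glucose sensing and repression genes did not pass as a whole (camera adjusted p = 0.716), and 2 of its members passed adjusted over the list alone. STD1, a regulator in the glucose induction pathway, stood at 105 ± 49.2 in galactose and 464 ± 12.8 in glucose (adjusted p = 0.165 over all probe sets). The repressor gene MIG2 lay under the floor in galactose and at 47.8 ± 15.4 in glucose (adjusted p = 0.203); both were chosen after their values were seen. The invertase gene SUC2 stood at 1544 ± 469 and 3056 ± 674 (adjusted p = 0.510), and the hexokinase gene HXK2, also chosen afterwards, at 2187 ± 307 and 4194 ± 72.5 (adjusted p = 0.305). The general repressor gene TUP1 stood at 1675 ± 235 and 1816 ± 90.7 (adjusted p = 0.904).

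**Figure D1:**
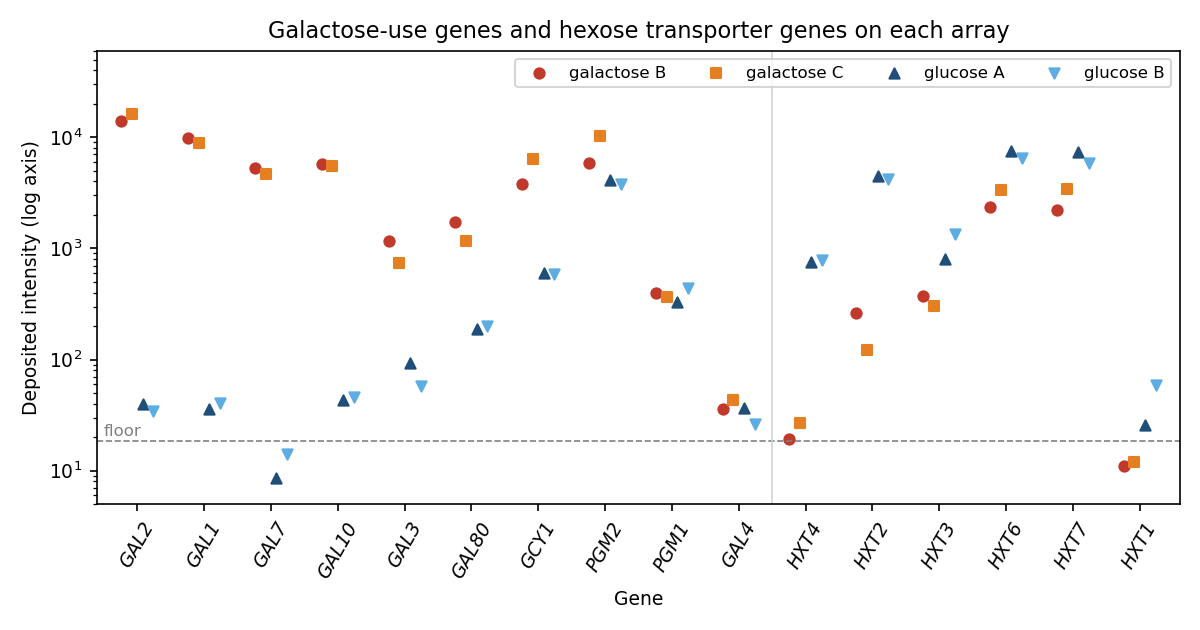
Deposited intensity (log axis) of galactose-use genes and of hexose transporter genes on each of the 4 arrays, 1 point per array, with the floor of 18.5 as a dashed line. GAL2, GAL1 and GAL10 lie 126-fold to 406-fold higher on the galactose arrays and GAL7, under the floor in glucose, at least 271-fold, while HXT4 and HXT2 lie 33.6-fold and 24.4-fold lower.

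Probe sets of Ty2 retrotransposons, mobile elements present in many copies, were also higher in galactose. Of 41 tested probe sets annotated to a Ty2 gene, 29 rose and 39 had both galactose arrays above both glucose arrays, with a median change of 7.58-fold (log2 2.92). Of these, 28 also list Ty1 genes (27 rose, median 7.63-fold) and 13 list Ty2 genes alone (2 rose, median 5.15-fold). The 37 probe sets that list Ty1 genes alone had a median change of 1.21-fold, and 3 of them rose; their log2 differences ran from -0.16 to 2.75. Some list 1 gene but are family probe sets, which can read other copies and the other family. Among these, the one listing YBL100W-B (annotated to Ty2) was 7.59-fold higher at 1347 ± 33.4 against 178 ± 19.3 (adjusted p = 0.0343), and the one listing YDR098C-B (annotated to Ty1) 6.75-fold higher (adjusted p = 0.0343). YJR027W (annotated to Ty1) was 5.90-fold higher on one probe set (adjusted p = 0.0481), while its other probe sets did not pass (adjusted p = 0.131 and 0.656). The reading frame YER138W-A, which was not assigned to a family, was 5.08-fold higher (adjusted p = 0.0451). YJR027W and YER138W-A lost their calls after quantile normalization (adjusted p = 0.0567 and 0.0555), with the floor at the 10th percentile (adjusted p = 0.0601 and 0.0569) and with no floor (adjusted p = 0.0747 and 0.0593). YER138W-A also lost its call when the Ty probe sets were left out of the adjustment. None of the 4 passed among probe sets that name 1 gene, where YBL100W-B and YDR098C-B had adjusted p = 0.0614. Copies of these elements are nearly identical, so the arrays cannot say which copies contribute, and the families were assigned after the values were seen.

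**Figure D2:**
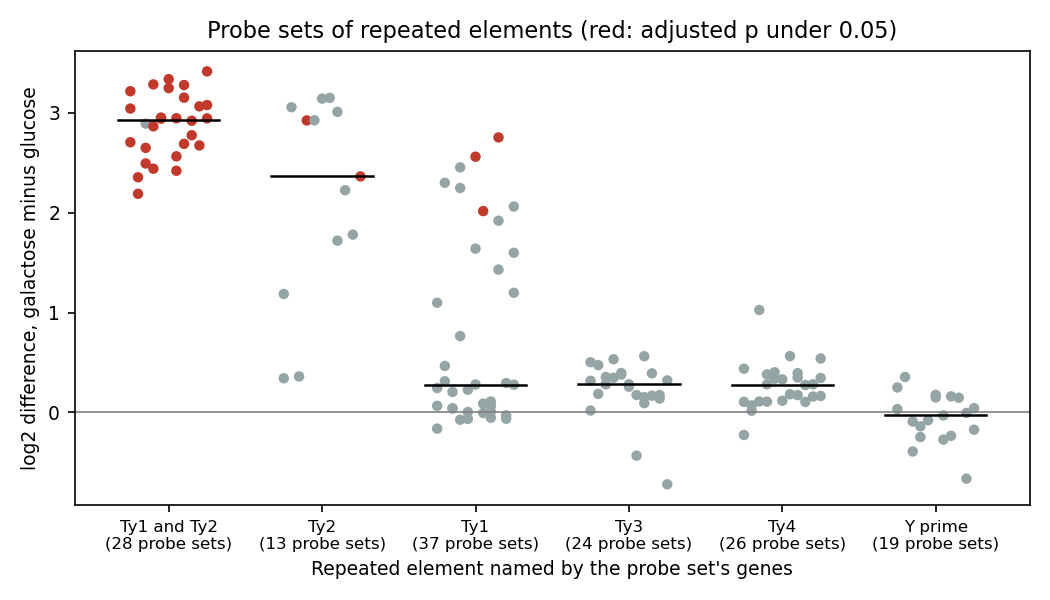
log2 difference (galactose minus glucose) of each probe set that lists genes of a repeated element family, with the family's median as a black line and probe sets past the threshold in red. The Ty1 and Ty2 probe sets centre on 2.93 and the Ty2 probe sets on 2.36, while the medians of Ty1, Ty3, Ty4 and the subtelomeric Y prime elements are 0.28, 0.28, 0.28 and -0.03.

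In total 58 of 7302 tested probe sets rose in galactose and 3 fell (limma, adjusted p under 0.05), and at an unadjusted p under 0.05 there were 313 higher and 316 lower, where chance gives 365 in both directions together. Of the 58, 32 list Ty1 or Ty2 genes, 16 have no listed gene and 10 name 1 gene outside these elements. All 16 have probe names with the ending _f_at, as the family probe sets of Ty genes named above do, but what they read is not known here. The 10 include YER138W-A, which was not assigned to a family and is also read by such a probe set. The 3 that fell were HXT4, HXT2 and a probe set that lists several genes, which was at least 11.7-fold lower. Both galactose arrays lay above both glucose arrays for 17.0% of probe sets and below them for 22.1%, where chance gives 16.7% each way. No probe set passed when any 1 of the 4 arrays was left out, and 7 rose when the Ty1 and Ty2 probe sets were left out of the test.

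Genes of the phosphate starvation response were higher in galactose. Of 13 tested members, 12 had both galactose arrays above both glucose arrays and 12 passed adjusted over the list alone, while 0 passed over all probe sets. The list rose with a median change of 2.97-fold (log2 1.57, camera adjusted p = 3.49e-16, and adjusted p = 0.439 with an estimated correlation). Of the polyphosphate synthesis genes, VTC1 stood at 8124 ± 962 against 2947 ± 348 (2.76-fold, adjusted p = 0.105) and VTC4 at 2853 ± 79.8 against 1064 ± 53.9 (2.68-fold, adjusted p = 0.0915). Larger ratios, chosen after their values were seen, were those of the transporter genes GIT1 (20.8-fold, adjusted p = 0.125) and PHO84 (7.89-fold, adjusted p = 0.387). PHO84 varied between the glucose arrays, at 1238 in glucose A and 242 in glucose B, and stood at 4821 and 3862 in galactose.

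Genes that respond to oxygen were higher in galactose only as a list, and 0 members passed over all probe sets. The list mixes genes known from growth at low oxygen with genes used with oxygen, such as CYC1. Its direction is therefore not that of low-oxygen genes alone. The list of 16 anaerobic and oxygen-responsive genes rose as a list (median 1.23-fold, camera adjusted p = 0.00683, and adjusted p = 0.488 with an estimated correlation), with 6 members apart upward, 2 apart downward and 3 passing adjusted over the list alone; it lost its call without galactose C (adjusted p = 0.0558), where its log2 median of 0.30 fell to 0.11, and with camera on ranks (adjusted p = 0.0815). The 3, chosen after their values were seen, were DAN1, a cell wall mannoprotein gene (361 ± 62.7 against 31.1 ± 27.5, adjusted p = 0.105), ANB1, a translation factor gene (330.4 ± 202 against 34.8 ± 19.0, adjusted p = 0.201), and PAU7 (922 ± 44.8 against 378 ± 94.5, adjusted p = 0.243). CYC1, a cytochrome c gene used with oxygen, stood at 8215 ± 2629 and 9816 ± 1492 (adjusted p = 0.817). The cell wall list also rose (19 members, median 1.12-fold, camera adjusted p = 0.00228, and adjusted p = 0.460 with an estimated correlation), and its log2 median of 0.16 fell to 0.10 without galactose C and to 0.08 without glucose A. Its highest members were the mannoprotein genes DAN1 and TIR4 (1198 ± 47.7 against 286 ± 239, adjusted p = 0.426), also chosen afterwards, which are known for anaerobic expression. The main wall protein genes CCW12 and SED1 stood 1.09-fold and 1.15-fold higher (adjusted p = 0.885 and 0.811).

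Lists of growth genes were lower in galactose, with different shares of the difference on each galactose array. The 43 ribosome biogenesis genes fell with a median change of 2.02-fold (camera adjusted p = 3.98e-13, and adjusted p = 0.781 with an estimated correlation), 27 with both galactose arrays below both glucose arrays and 0 past the threshold singly. GAR1, which modifies ribosomal RNA, stood at 1549 ± 610.3 against 3671 ± 152 (adjusted p = 0.374), and NSR1, a nucleolar protein gene chosen after its values were seen, at 585 ± 465 against 1586 ± 516 (adjusted p = 0.591). Relative to the glucose mean, the median of the list was -0.36 on galactose B and -1.72 on galactose C on the log2 scale, so that without galactose C the change is -0.36. The 81 ribosomal protein genes fell by a median of 1.27-fold (camera adjusted p = 5.44e-09, and adjusted p = 0.781 with an estimated correlation), with array medians of -0.08 and -0.61, and lost the call without galactose C. RPL39 stood at 14062 ± 2175 against 18884 ± 315 (adjusted p = 0.633). The 70 mitochondrial ribosomal protein genes fell by 1.48-fold (camera adjusted p = 4.65e-14, and adjusted p = 0.781 with an estimated correlation), 52 of them apart downward, but here galactose B was the lower array, at -0.84 against -0.28, the change without galactose B. The 50 amino acid synthesis genes (1.32-fold, camera adjusted p = 0.000899) and the 15 G1 and S phase genes (1.25-fold, camera adjusted p = 0.0477) also fell as lists, with adjusted p = 0.781 and 0.833 with an estimated correlation, and both lost their call without galactose C and without glucose B. The G1 and S phase list passed in 5 of 8 other settings of the fit; it lost its call after quantile normalization (adjusted p = 0.0559), with the floor at the 40th percentile (adjusted p = 0.0724) and among probe sets above the floor on all arrays (adjusted p = 0.0628). Without galactose C its log2 median turned to 0.04, and that of the amino acid list, -0.40, went to -0.08.

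Storage, stress and cell-state lists made up the rest of those past the threshold. The 16 trehalose and glycogen genes rose as a list (median 1.37-fold, camera adjusted p = 0.00334, and adjusted p = 0.781 with an estimated correlation), with medians of 0.01 on galactose B and 0.95 on galactose C. The 20 heat shock genes did likewise (1.15-fold, camera adjusted p = 0.0359, and adjusted p = 0.781 with an estimated correlation), at 0.05 and 0.41. Both lost their call without galactose C and without glucose B. TPS1, the trehalose phosphate synthase gene, stood at 4769 ± 2074 against 3221 ± 234 (adjusted p = 0.752), and HSP12 at 16957 ± 4426 against 15223 ± 1943 (adjusted p = 0.912). Daughter and early G1 genes rose as a list (10 members, 1.31-fold, camera adjusted p = 0.00214, and adjusted p = 0.593 with an estimated correlation; call lost without galactose C), with the chitinase gene CTS1 at 5155 ± 659 against 3772 ± 462 (adjusted p = 0.640). So did the meiosis (1.15-fold, camera adjusted p = 0.00376), haploid and mating (1.14-fold, 0.0163) and sulfur and methionine lists (1.19-fold, 0.0305), with adjusted p = 0.593, 0.690 and 0.781 with an estimated correlation. With the floor at the 40th percentile all 3 lost their calls. The meiosis list kept its call with any 1 array left out, but its log2 median of 0.21 fell to 0.09 without galactose C and rose to 0.34 without galactose B; it was 0.09 with no floor and 0.53 among probe sets above the floor on all arrays. The mating list passed in 5 of 8 other settings of the fit, and also lost its call with the floor at the 10th percentile (adjusted p = 0.0715), with no floor (adjusted p = 0.0528) and without glucose B (adjusted p = 0.185). The sulfur list lost its call without any 1 of galactose B, galactose C and glucose B, and its log2 median of 0.25 turned to -0.07 without glucose B and rose to 0.74 without glucose A.

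**Figure D3:**
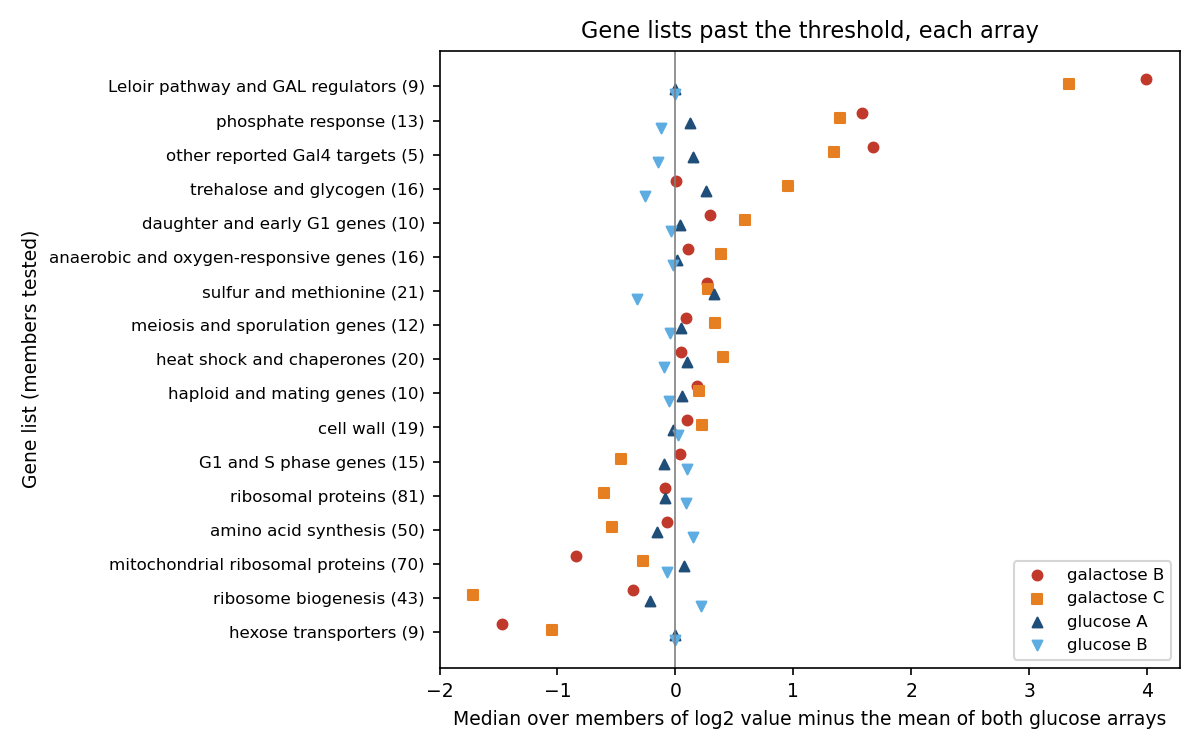
Median over the members of each gene list past the threshold of the log2 value minus the mean of both glucose arrays, 1 point per array, with the number of members tested in brackets. Ribosome biogenesis genes lie at -0.36 on galactose B and -1.72 on galactose C, while phosphate response genes lie at 1.58 and 1.39.

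Central carbon metabolism beyond galactose entry did not pass. The glycolysis list (16 genes, median 1.03-fold, camera adjusted p = 0.934) held ENO2 at 17358 ± 816 against 16792 ± 1163 and GPM1 at 13469 ± 1148 against 11910.0 ± 844. The fermentation genes ADH1 (12050.0 ± 814 against 11847 ± 432) and PDC1 (8304 ± 249.9 against 7813 ± 1982) stood 1.02-fold and 1.08-fold higher. The TCA cycle, respiratory chain, gluconeogenesis and pentose phosphate lists had camera adjusted p of 0.560, 0.809, 0.851 and 0.951. Genes of these lists were not all low in glucose. The gluconeogenesis gene PCK1 stood at 6755 in glucose A and 1854 in glucose B, against 1809 in galactose B and 3142 in galactose C. All 16 genes of the gluconeogenesis list were higher in glucose A than in glucose B (median ratio 3.30, chosen after the values were seen). How far glucose repressed such genes in the glucose samples was not tested. A list that did not pass therefore does not exclude an effect of the sugar. The respiratory chain median was -0.01 while the test gave an upward direction, and the glycolysis median was 0.04 while the test gave a downward one. In all, 18 of 35 lists did not pass, with medians from -0.28 (fatty acid oxidation) to 0.23 (glycerol synthesis) on the log2 scale. They include the lists for sucrose and maltose use, oxidative stress, ergosterol, iron, zinc and copper, histones, G2 and M phase, and quiescence. The 10 reference genes differed by 1.02-fold (TFC1) to 1.48-fold (SPT15), with adjusted p from 0.633 to 0.979, and ACT1 stood at 9777 ± 1042 against 8213 ± 247.

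Some signs of RNA handling differed with the medium and so with every list above. The ratio of the ACT1 3' to 5' control probe sets was 2.14 ± 0.372 in galactose and 1.29 ± 0.275 in glucose, with no overlap between the media. Of the 17 lists past the threshold with the preset correlation, 11 higher and 6 lower, 0 passed with an estimated correlation and 1 (Leloir pathway and GAL regulators) with fry. The correlation was estimated on 2 residual degrees of freedom. With it even the GAL list, with GAL2 406-fold higher, did not pass, so it cannot decide against a list. That does not make the calls with the preset correlation firmer. Ribosome biogenesis, with a camera adjusted p of 3.98e-13 at the preset correlation, had an adjusted p of 0.711 with fry.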

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

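Some of the array's own control probe sets, which enter no test above, differed between the media and others overlapped. These values were looked up after the comparison was seen. The ratio of the 3' to the 5' probe set was 1.67-fold higher in galactose for ACT1 (2.41 on galactose B, 1.88 on galactose C, 1.097 on glucose A and 1.49 on glucose B) and 1.80-fold higher for SRB4 (27.2, 26.6, 10.3 and 21.6). For SPT15 the arrays overlapped (1.91, 1.88, 2.13 and 1.38). The 12 probe sets of the bacterial poly-A spikes, which serve as labelling controls, had a geometric mean 1.51-fold higher in galactose (274, 182, 144 and 152), and every one of them had both galactose arrays above both glucose arrays. The hybridisation spikes overlapped (395, 347, 402 and 381). The 5 probe sets of 18S ribosomal RNA overlapped too, with a geometric mean of 68.0, 224, 106 and 82.7, and were highest on galactose C.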

How the results depend on the processing

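The Ty and single-gene subsets were chosen after the data were seen; the other settings were planned. Values as deposited are the main setting, so that alternative adds nothing. No paired analysis was possible because the media share only 1 replicate letter. Against 58 probe sets higher and 3 lower, quantile normalization gave 25 higher, the floor at the 10th percentile 32 and no floor 26, all among the 58. An adjusted p under 0.01 gave 4 and 0, and under 0.1 it gave 94 and 6. Without the Ty1 and Ty2 probe sets 7 rose, and among probe sets that name 1 gene, or with 1 probe set per gene, 5 rose and 1 fell; fewer low p-values then enter the adjustment. With 1 array left out (1 residual degree of freedom, the lone array assumed to vary like the other medium's) both counts ranged from 0 to 0, with 524 higher and 743 lower at an unadjusted p under 0.05 without galactose B and 186 and 153 without glucose B. The GAL list kept its direction, with a median of 3.26 to 4.99, and its adjusted p ran from 4.15e-20 to 0.365, the latter with an estimated correlation (median 3.66). The counts of 11 lists higher and 6 lower became 0 and 0 with an estimated correlation and 1 and 0 with fry. Leaving out 1 array gave 6 (without galactose C) to 16 lists higher, 7 without glucose B, and 4 to 6 lower. Of 159 values of the 15 called genes with all arrays, 118 kept the call, 41 lost it and 0 changed sign; with 1 array left out, 0 of 60 passed and 60 kept their sign. Of 1524 values of the other named genes, 1 passed (DAN1, floor at the 40th percentile) and 64 changed sign without passing. The cause was not tested except where stated. Genes near the floor of 18.5 are limited by signal over background.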

Other observations

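Arrays of the same medium, taken at the same optical density, differed in genes of slow growth and of carbon sources other than sugar; these values were chosen after they were seen and have no test, with 1 array on each side. All 16 gluconeogenesis and glyoxylate genes were higher in glucose A than in glucose B, with a median ratio of 3.30, and 14 of 15 fatty acid oxidation genes were too, with a median ratio of 2.31. The alcohol dehydrogenase gene ADH2, which is known to be repressed by glucose, stood at 2495 in glucose A and 213 in glucose B, and the acetate transporter gene ADY2 at 1209 and 153. The heat shock list was less uniform: HSP26 (839 and 125) and HSP30 (4247 and 616) were higher in glucose A, but only 13 of its 20 members were, with a median ratio of 1.14. Between the galactose arrays, galactose C had the higher values for 16 of 16 TCA cycle genes (median ratio 1.83), 16 of 16 trehalose and glycogen genes (2.03) and 12 of 13 quiescence genes (3.47). HSP26 stood at 1059 in galactose C and 230.2 in galactose B. Ribosome biogenesis genes went the other way, lower in galactose C for 43 of 43 members and lower in glucose A for 42 of 43.

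Phosphate response and Ty2 levels did not follow this division of the arrays. The phosphate list's median difference was 1.42 to 1.71 on the log2 scale over the 4 pairs of a galactose and a glucose array, and its size was 0.24 and 0.25 between arrays of 1 medium. For the probe sets of Ty2 genes the pairs gave 2.63 to 2.98, and arrays of 1 medium differed by 0.32 and 0.03.

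The rise of Ty2 probe sets was weighed against 3 explanations; the tests of genomic DNA and of growth state were chosen after the values were seen, the test of scaling before. Genomic DNA in the galactose RNA would raise other multi-copy elements too, but the 69 probe sets of Ty3, Ty4 and Y prime had a median log2 difference of 0.17, with 0 past the threshold, against 2.92 for Ty2. The 37 probe sets that list Ty1 genes alone had a median of 0.28, with 3 past the threshold. Copy numbers in this strain were not measured, so the rise that such DNA would give each family is not known. Scaling that depends on brightness is argued against by a Ty2 median of 2.93 after quantile normalization. The growth state that separates the arrays within each medium is argued against by 2.98 between galactose B and glucose B. These are the arrays lower in most trehalose, glycogen and quiescence genes. A growth difference that goes with the medium cannot be told apart from the sugar. An effect of the medium on Ty2 transcripts remains a hypothesis, and a difference between the cultures unrelated to sugar, such as their Ty2 copy number, was not tested. The 3 splits of the 4 arrays into pairs are too few for a share under 0.05; the real one gave 61 probe sets and the highest other 0.

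The lower level of ribosome biogenesis genes in galactose was weighed in the same way, with all tests but that of scaling chosen after the values were seen. Scaling is argued against by a median of -1.01 after quantile normalization. RNA degradation as read from ACT1 is argued against only for the difference between the galactose arrays. There, galactose B has the higher 3' to 5' ratio and yet list values 1.28 above those of galactose C on the log2 scale. The SRB4 ratio hardly separates these arrays (27.2 and 26.6). Between the media the test cannot decide, since the ACT1 and SRB4 ratios were higher on both galactose arrays. The 18S signal cannot tell, so RNA make-up or labelling is not ruled out: in each medium the array with more 18S had list values lower by at least 0.44, yet galactose B had the least 18S and list values under both glucose arrays. A growth or stress state that differs between samples of the same medium may account for it. The smallest difference between a galactose and a glucose array was 0.12 (galactose B and glucose A), under the 1.28 within galactose. This explanation needs separate cultures, which the labels do not state. Whether the sugar adds to any of these stays open with 2 arrays per medium.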
